A study of Homo sapiens with 4 samples.

How the data were processed

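The series measured messenger RNA on 4 expression arrays of HuH7, a human hepatocellular carcinoma cell line. The labels place 2 arrays in the parental group, here F0 (1) and F0 (2), 1 array in F6 and 1 array in F12. F6 and F12 are the cells obtained after 6 and 12 rounds of regrafting treated tumors in immunodeficient mice. Per the labels' protocols, total RNA came from tissue specimens and was amplified and labelled with biotin by a 3' in vitro transcription kit.

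The deposited values are on the log2 scale, 1 per probeset and array. Per the submitters' processing notes they were made with RMA, which corrects background, quantile-normalizes probes and summarizes them per probeset, in the affy package. Versions and settings are not given in the sources used here. The medians of the 4 arrays lay between 4.67 and 4.85, and the maxima between 14.43 and 14.58. Values of this kind have no count or depth behind them, so the number of arrays limits the precision.

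The table holds 54613 probesets. The platform annotation gave 1 gene symbol for 41091 of them, several for 1801 and none for 11721. Of the probesets with 1 symbol, 41037 matched the RefSeq gene table of assembly GRCh38.p14 by Entrez number, and this match altered 0 symbols. Each of 19775 genes was represented by the probeset with the highest mean over the 4 arrays, passing over probesets whose names mark possible cross-hybridization wherever the gene had another. For 419 genes only probesets of that kind existed. Genes with near-identical copies, such as TMSB4X, the metallothionein MT1M and the REG lectins, can share probes with those copies, and their values are uncertain to that extent. The array-quality check planned on the control probesets was not run, since the table used here holds 0 such rows.

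Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. F6, F12 and F0 were fitted as 3 groups, which leaves 1 residual degree of freedom, from the F0 pair alone. F6 and F12 are thus assumed to vary like the F0 pair. The arrays did not bear this out. About a linear fit to the F0 arrays across genes the SDs were 0.53 for F6 and 0.58 for F12, against 1.42 per F0 array. In each main comparison fewer genes had an unadjusted p under 0.05 than chance alone would give, so these p-values are not well calibrated. In this fit limma moderated the spread fully to 1 value pooled over genes. Every gene therefore has the same SE (1.74 for F6 or F12 against F0), and its own F0 spread plays no part. The mean of F6 and F12 was also set against F0 as 2 groups with 2 residual degrees of freedom. The labels do not say whether the 2 F0 samples came from separate cultures or tumors, so p-values measure only the spread between these samples, which may be technical. On simulated data for F12 against F0, with 19775 genes and the spread of the F0 pair (SD 1.42), limma recovered 0% of 50 genes changed by log2 2, 4% of those changed by 4, 38% at 6 and 76% at 8. With a spread of 0.25 it recovered 100% at each of these sizes.

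A total of 48 gene lists, with 1129 entries, were fixed before the data were examined, along with the comparisons and tests. For each list the median log2 difference was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called standing apart below percentile 2.5 or above percentile 97.5, which describes these arrays. If genes varied independently, 2.4 of 48 lists would do so by chance. On values simulated in that way 10 of 200 unshifted lists were called, and 50 of 50 lists shifted by log2 1 were called. Genes of a real list can move together, as mitotic genes did between the F0 arrays (median 3.78). More lists than 2.4 can thus stand apart without an effect. The limma test camera was run beside this ranking with a preset correlation of 0.01 and with an estimated correlation. The estimated correlation rests on the 1 residual degree of freedom of the 3-group fit, so that setting could hardly call any list. A list that it did not call is therefore not shown to be unchanged. The preset value of 0.01 takes list members to be nearly independent, so its calls are not firm either.

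The planned rule named the 10 genes with the largest increase and decrease past the adjusted p, and 9 genes whatever they did (KDR, FLT1, FLT4, AURKA, AURKB, AFP, ALB, VEGFA and EZH2). No gene passed, so other genes are named by size, a choice made after their values were seen. These are the genes farthest above or below both F0 arrays, with a log2 value of at least 6 on 1 array and every usable probeset on the same side of the F0 mean. Members of gene lists are named where they lay at least 2-fold beyond both F0 arrays, or as examples with their values. The count of genes beyond both F0 arrays was also added after the F0 arrays were seen to differ. So was an adjustment that subtracts from F6 and F12 the value expected from their position between the F0 arrays (a linear fit across genes), with random lists matched on the F0 difference as well in 10 bins of each.

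Alternatives tried were a variance trend, a minimum change of 2-fold in the test, the mean of a gene's probesets, all probesets singly, a minimum log2 value of 6 on 1 array, a repeated quantile normalization, centring on the median, the position between the F0 arrays as a covariate for resistant against parental samples, and leaving out arrays. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.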

Results

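Gene expression was measured in HuH7 liver cancer cells before and after serial treatment in mice. Tumors of these cells were treated with JNJ-28841072, an inhibitor of vascular endothelial growth factor receptors and aurora kinases, and resistant tumors were regrafted 6 times (F6) or 12 times (F12). The phenotype label of the F6 and F12 samples names resistance to sorafenib instead, and the sources used here do not settle which drug is meant. The parental cells (F0) had 2 arrays, and F6 and F12 had 1 array each, so F6 and F12 have no replicate check of their own. No array came from untreated tumors regrafted as often, so treatment and regrafting cannot be told apart. Values below are log2 signals, and a difference of 1 is 2-fold. Signals under 6 are treated as near background (the array medians lay between 4.67 and 4.85), so a difference from such a signal is a limit and not an exact fold.

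The parental pair alone sets the error of the comparisons among F0, F6 and F12. When both resistant samples are set against F0, the difference between F6 and F12 enters the error as well. The spread of the parental pair was wide. F0 (1) and F0 (2) differed by at least 4-fold for 4810 of 19775 genes, with 3794 higher in F0 (2) and 1016 lower. SLC7A11, the cystine transporter, read 3.60 on F0 (1) and 10.60 on F0 (2), and SLC38A1, a glutamine transporter, read 4.80 and 11.82. The liver proteins albumin (ALB, 10.18 and 13.75) and alpha-fetoprotein (AFP, 8.88 and 13.73) were also higher on F0 (2). In the opposite direction, the ribosomal RNA precursor RNA45SN5 read 12.96 on F0 (1) and 6.87 on F0 (2). The SD of the difference between the F0 arrays was 2.01 across genes, and their Pearson r across genes, which are not independent replicates, was 0.687.

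F12 resembled F0 (2) more than the parental arrays resembled each other. The r across genes was 0.976 for F12 with F0 (2), 0.917 for F6 with F0 (1), 0.873 for F6 with F0 (2) and 0.675 for F12 with F0 (1). On a scale from F0 (1) at 0 to F0 (2) at 1, fitted across genes, F6 lay at 0.411 and F12 at 0.963. Among the 4810 genes with a 4-fold F0 difference, F6 lay between the F0 arrays for 4544 (94.5%) and F12 for 2550. RNA45SN5 followed the same order, at 11.92 on F6 and 6.54 on F12.

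**Figure D1:**
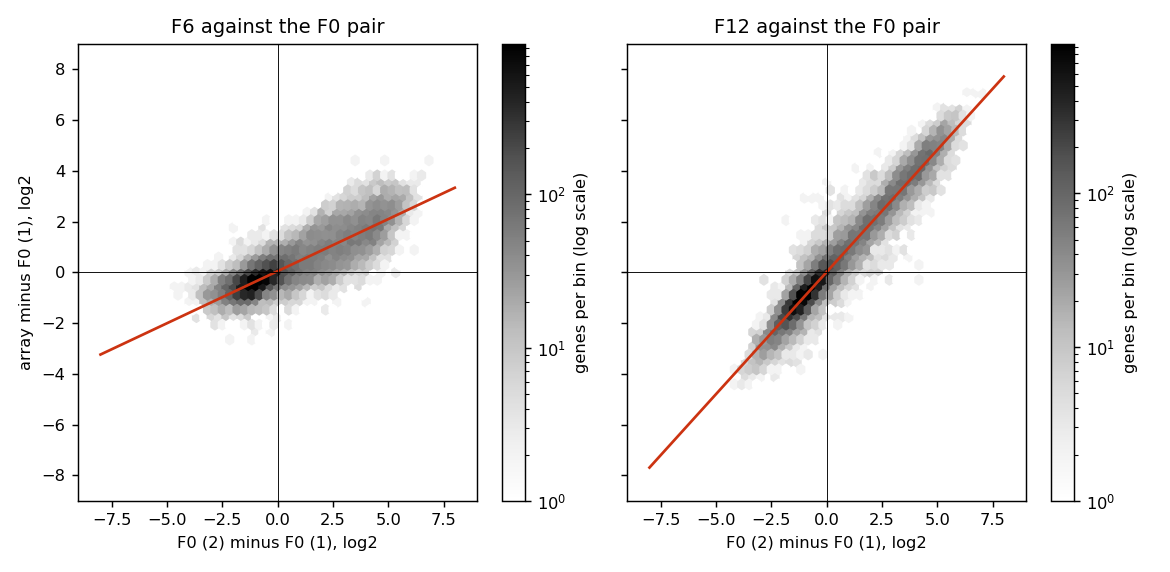
Difference of F6 (left) and F12 (right) from F0 (1) against the difference between the 2 F0 arrays, both in log2, with the number of genes per hexagon in grey on a log scale and the linear fit in red. The slope is 0.411 for F6 and 0.963 for F12.

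The series description states that 119 genes in F6 and 2199 in F12 were over 4-fold higher than in parental cells. Against the F0 mean, 37 genes (141 probesets) were at least 4-fold higher in F6 and 1580 genes (3004 probesets) in F12. The parental array, the level (genes or probesets) and the filter behind the stated counts are not given, so these counts cannot be matched to them like for like. At least 4-fold lower were 90 genes in F6 and 209 in F12. These counts depended on the parental array used. F12 had 3761 genes 4-fold higher than F0 (1) and 113 higher than F0 (2), and F6 had 1345 and 388. Genes 4-fold above both F0 arrays numbered 11 in F6 and 74 in F12, and genes 4-fold below both numbered 12 and 42.

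The comparison of F6 with F0 asks what differed after 6 rounds of treatment and regrafting. TMSB4X, LGALS1 and SFN were over 2-fold above both parental arrays, and REG3A, REG1A and the chemokines CXCL1 and CXCL3 over 2-fold below both. TMSB4X, which encodes the actin-binding peptide thymosin beta 4, read 13.17 on F6 against 7.56 and 9.19 on F0 (1) and F0 (2). Galectin-1 (LGALS1) read 10.42 against 8.0 and 6.25, and 14-3-3 sigma (SFN) 11.48 against 9.35 and 8.45. CYP2B6, a drug-metabolizing cytochrome, read 9.05 against 5.77 and 6.76. The regenerating lectins REG3A (4.41 against 8.08 and 9.59) and REG1A (4.21 against 7.44 and 9.78) were lower, though with the mean of its probesets the difference of REG3A from the F0 mean was -2.23 in place of -4.43. So were the creatine transporter SLC6A8 (7.11 against 9.44 and 9.79) and the liver esterase CES1 (6.03 against 8.39 and 9.01).

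Cholesterol synthesis genes were the list highest in F6, with a median 1.00 above the F0 mean (percentile 100, 18 genes measured). At the preset correlation camera called this list and each of the other 4 lists described here for F6. With an estimated correlation it called none of them. The list median was 0.34 above F0 (1), where it did not stand apart, and 0.90 above F0 (2), where it did, and 2 of the 18 genes were at least 2-fold above both. INSIG1, which holds sterol regulators in the endoplasmic reticulum, read 9.58 against 7.55 and 7.15, and the reductase DHCR7 read 11.45 against 10.19 and 8.84. MAPK pathway output genes (median 0.53) and Wnt pathway target genes (median 0.43) also had medians above both F0 arrays, but the MAPK list stood apart against neither F0 array alone and the Wnt list only against F0 (1). The Wnt targets TBX3 and SP5 were each over 2-fold above both, TBX3 at 7.98 against 6.85 and 6.83 and SP5 at 6.90 against 5.87 and 4.76. NF-kB and cytokine genes stood lower (median -0.22; against F0 (2) alone, -0.12, they did not stand apart), with 4 of 22 members at least 2-fold below both F0 arrays. Those were the neutrophil chemokines CXCL1 (5.12 against 7.46 and 8.94), CXCL3 (4.79 against 7.45 and 8.0) and CXCL8 (4.14 against 5.70 and 7.07), and the siderophore-binding protein LCN2 (5.61 against 7.49 and 7.40). CXCL8 was near background on F6 and on F0 (1), so its difference from F0 (1) is not evidence of a decrease. Complement and coagulation genes had a median of -0.47, which was -0.02 against F0 (1), where they did not stand apart, and -1.03 against F0 (2).

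In limma, 0 genes passed the adjusted threshold for F6 against F0, and 7 had an unadjusted p under 0.05, with a smallest adjusted p of 1. Here and in the other comparisons, fewer genes had an unadjusted p under 0.05 than chance alone would give, with the error taken from the wide F0 pair. Of 48 lists, 13 stood apart, but 6 of these had medians of opposite sign against F0 (1) and F0 (2), among them mitotic genes (1.78 and -1.20).

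The comparison of F12 with F0 asks the same after 12 rounds. BEX1 and VCAM1 were far above both parental arrays in F12, and MAPK pathway output, DNA replication and glycolysis genes had medians below both, while insulin-like growth factor axis genes had a median above both. BEX1, a brain-expressed X-linked gene, read 11.99 on F12 against 4.58 and 4.19 on the F0 arrays. VCAM1, a vascular adhesion molecule, read 9.46 against 4.16 and 3.69. HKDC1, a hexokinase-domain protein, read 9.95 against 6.07 and 6.24 (3.80 above the F0 mean, and 1.91 with the mean of its probesets), and the complement inhibitor SERPING1 read 9.83 against 6.47 and 6.45. ID1, an inhibitor of helix-loop-helix transcription factors, read 9.25 against 13.73 and 13.03. The glutathione peroxidases GPX2 (6.84 against 11.80 and 10.75) and GPX3 (5.15 against 11.96 and 8.45) were lower, as was the monoglyceride lipase MGLL (5.25 against 9.60 and 9.42). With the mean of its probesets the difference of GPX2 from the F0 mean was -2.90 in place of -4.43.

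MAPK pathway output genes had a median of -0.84 in F12 against the F0 mean (percentile 0.1), at -0.91 against F0 (1), where they did not stand apart, and -1.29 against F0 (2). With an estimated correlation in camera the adjusted p = 0.895 for this list and for each of the other 9 lists that stood apart in F12. At least 2-fold below both F0 arrays were 6 of 19 members, including the transcription factors ETV4 (4.77 against 10.41 and 7.17) and ETV5 (6.18 against 8.09 and 9.08) and the feedback inhibitor SPRY4 (4.91 against 6.35 and 6.21). DNA replication genes had a median of -0.74 (against F0 (1) alone, -0.44, they did not stand apart), with 9 of 29 members at least 2-fold below both, against 1.37% of all genes. The ribonucleotide reductase subunit RRM2 read 7.91 against 11.13 and 10.92, and the licensing factor CDT1 read 5.94 against 10.73 and 7.08. Glycolytic enzymes had a median of -0.98, at -1.48 against F0 (1) and -0.66 against F0 (2), with ALDOA at 10.22 against 13.82 and 12.21 and PGK1 at 10.15 against 12.70 and 12.14. Unfolded protein and integrated stress response genes stood higher (median 1.59), at 2.16 against F0 (1) and 0.41 against F0 (2). The chaperone HYOU1 read 11.92 against 10.06 and 10.23 and the disulfide isomerase PDIA4 12.63 against 9.41 and 11.50. Insulin-like growth factor axis genes had a median of 1.27, at 1.87 and 0.29. With the mean of probesets this median was 0.45, and that of the unfolded protein and integrated stress response genes 0.96, and both lists still stood apart. Core and linker histone genes had a median of -0.88, which was -1.83 against F0 (1) and -0.12 against F0 (2), where they did not stand apart. Immediate early and heat shock genes, a sign of tissue handling, also stood lower (median -0.60, percentile 2.42), at -0.96 against F0 (1), where they did not stand apart, and -0.27 against F0 (2), where they did. At the preset correlation camera called the MAPK output, replication, glycolysis, stress response, insulin-like growth factor and histone lists. It did not call the immediate early and heat shock list, nor the NF-kB, mesenchymal and imprinted lists. NF-kB and cytokine genes (-0.54) and mesenchymal genes (-0.55) were the other lists standing lower, and imprinted genes (0.23) the other standing higher. Of these 3, NF-kB and cytokine genes stood apart only against F0 (2), imprinted genes only against F0 (1), and mesenchymal genes against neither F0 array alone. With the mean of probesets the median of the mesenchymal genes was -0.26 and did not stand apart, and that of the imprinted genes reversed to -0.04.

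In limma, 0 genes passed for F12 against F0, 85 had an unadjusted p under 0.05, and the smallest adjusted p was 0.249, for BEX1 (log2 difference 7.61, SE 1.74, a limit since both F0 signals were near background). That SE is pooled over genes and is not the error of BEX1 itself, whose F0 arrays had an SD of 0.275. Of 48 lists 10 stood apart.

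**Figure D2:**
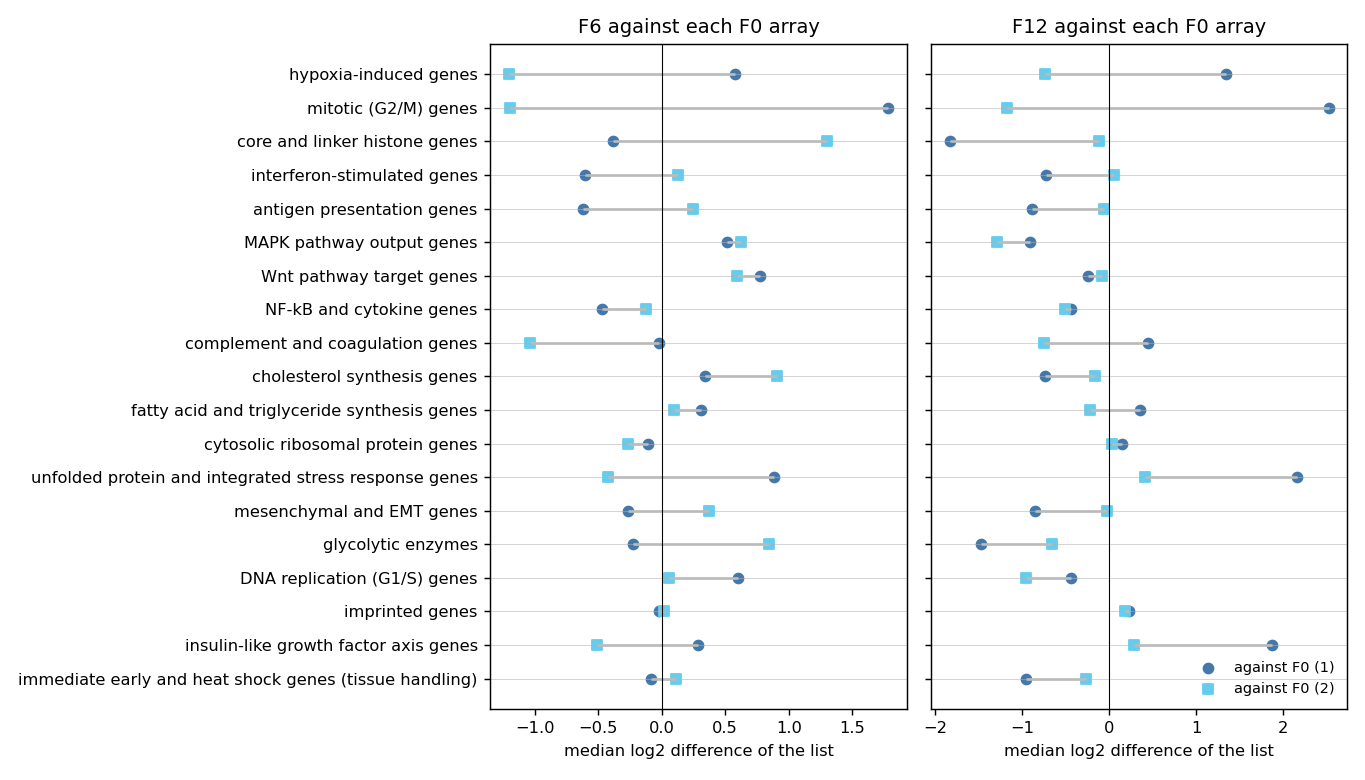
Median log2 difference of each gene list that stood apart in F6 or F12, against F0 (1) (circles) and F0 (2) (squares), with a line joining the 2 values. MAPK pathway output genes lie above both F0 arrays in F6 (0.51 and 0.63) and below both in F12 (-0.91 and -1.29), while mitotic genes change sign with the F0 array used.

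The comparison of F12 with F6 asks what differed between the earlier and later rounds. BEX1 read 6.59 on F6 and 11.99 on F12, and VCAM1, near background on F6, read 4.56 and 9.46. GPX3 read 11.19 on F6 and 5.15 on F12, GPX2 11.28 and 6.84, ID1 13.24 and 9.25, and RRM2 11.73 and 7.91. CXCL1 (5.12 on F6, 7.55 on F12) and CXCL3 (4.79 and 7.20) were lower in F6 than on the other 3 arrays. Cholesterol synthesis genes (median -1.27), MAPK pathway output genes (-1.15), DNA replication genes (-1.03), glycolytic enzymes (-1.43) and core and linker histone genes (-1.56) were lower in F12. So were macrophage and myeloid markers (-0.79, percentile 0.11) and mesenchymal genes (-0.77, percentile 0.28). Most of the macrophage and myeloid markers read under 6 on both arrays, so that difference lies mainly between signals near background. Neither list stood apart with the mean of probesets, and after adjustment for position between the F0 arrays only the macrophage list did. Unfolded protein and integrated stress response genes (1.25), DNA methylation and demethylation genes (1.51), insulin-like growth factor axis genes (0.99) and cytosolic ribosomal protein genes (0.32) were higher. After adjustment for position between the F0 arrays, the DNA methylation (-0.01) and insulin-like growth factor (0.02) lists did not stand apart. Hepatocyte metabolism genes stood high among random lists (percentile 97.7) with a median of -0.09. With an estimated correlation camera called none of the 12 lists that stood apart. At the preset correlation it called them except for the mesenchymal, insulin-like growth factor, ribosomal protein and hepatocyte metabolism lists. In limma 0 genes passed, 116 had an unadjusted p under 0.05, and the smallest adjusted p was 1. The 12 lists were among 48.

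Both resistant samples were also set against both parental samples. A gap of at least 4-fold separated F6 and F12 from the F0 pair for 10 genes, 5 higher and 5 lower. TMSB4X had the widest gap upward, followed by ICAM4, a red-cell adhesion molecule (7.69 on F6 and 8.09 on F12 against 5.13 and 4.76). The metallothionein MT1M (7.05 and 6.69 against 4.82 and 2.97) was also above both F0 arrays. REG3A, REG1A, LGALS14 and the thyroxine-binding globulin SERPINA7 (4.07 and 3.70 against 6.19 and 9.11) had wide gaps downward. Grouping the arrays as F0 (1) with F6 and F0 (2) with F12 gave 1843 such genes, and grouping F0 (1) with F12 and F0 (2) with F6 gave 1. In limma 0 genes passed, and 45 had an unadjusted p under 0.05.

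**Figure D3:**
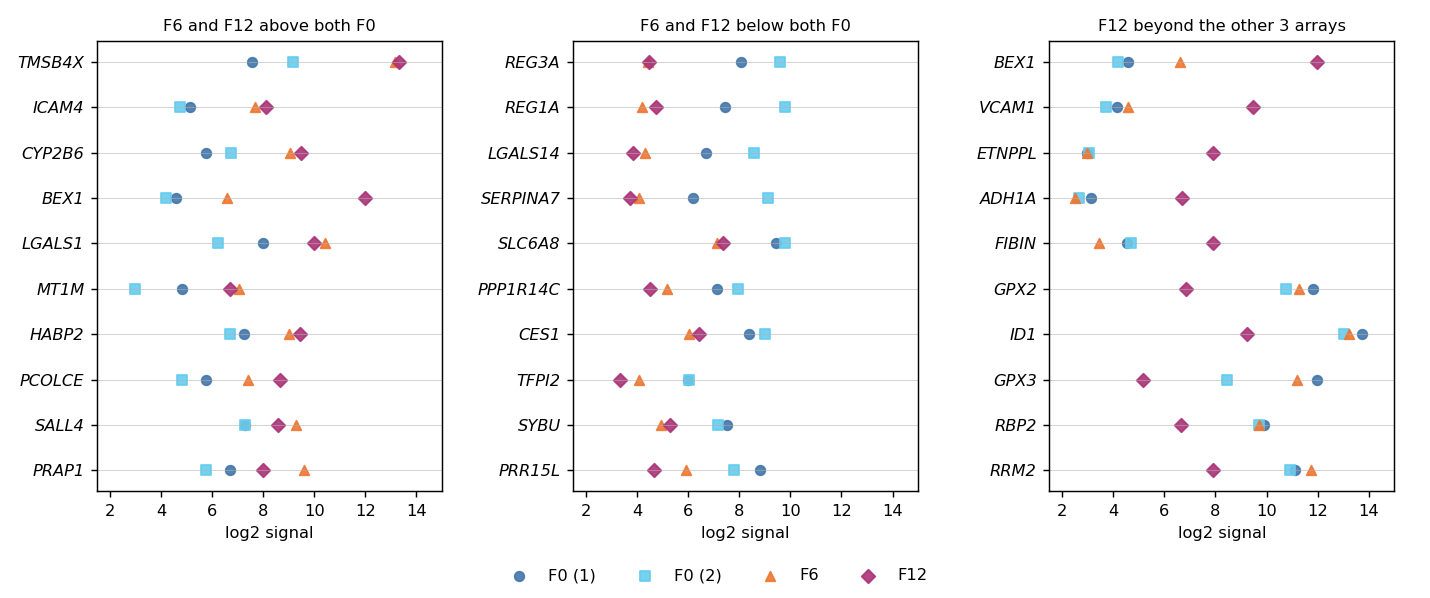
Log2 signal on each of the 4 arrays for the genes with the widest gap between both F0 arrays and both F6 and F12 (left and middle) and for genes where F12 lies farthest beyond the other 3 arrays (right). TMSB4X reads 13.17 on F6 and 13.31 on F12 against 7.56 and 9.19 on the F0 arrays.

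The differences of F6 and of F12 from the F0 mean had an r of -0.138 across genes and a covariance of -0.085. Unchanged groups were simulated with every array, F0 included, drawn independently at the spread of the F0 pair. They gave an r of 0.333 and a covariance of 1.01. The measured arrays were not independent in this way. F6 lay at 0.411 and F12 at 0.963 between the F0 arrays, with SDs about that fit of 0.53 and 0.58, against 1.42 per F0 array. The simulated r, covariance and gene count therefore cannot show whether F6 and F12 were less alike than unchanged groups. At least 2-fold higher in both were 270 genes and 2-fold lower in both were 115, against 2796 genes 2-fold the same way in both for the simulated unchanged groups, and 597 genes went opposite ways. Independent lists of the same sizes, which leave out the shared F0 arrays, would share 136.0 higher and 80.6 lower genes.

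The list of VEGF receptors, aurora kinases and sorafenib target kinases (16 genes measured) did not stand apart in F6 or F12. Its median in F12 was -0.94 against F0 (1) and -0.26 against F0 (2), and it stood apart without F0 (1) and after adjustment for position between the F0 arrays (adjusted median -0.28, percentile 0.46). With F12 at 0.963 on that scale, both set the list nearly against F0 (2) alone, so they are not separate support for the list. In F6 its median was -0.24 against F0 (1) and 0.62 against F0 (2), and camera called it higher against the F0 mean at the preset correlation (adjusted p = 0.049) but not with an estimated one (adjusted p = 0.943). With a minimum log2 value of 6 on 1 array it stood apart in both, higher in F6 (0.50) and lower in F12 (-0.83), and with the mean of probesets in F6 (0.31). F12 was lower than F6 by a median of -0.64, with an adjusted p of 0.00912 in camera at the preset correlation and an adjusted p = 0.971 with an estimated correlation. Among random lists this difference between F12 and F6 did not stand apart (percentile 6.63), but it did after adjustment for position between the F0 arrays (-0.36, percentile 1.04). KDR, which encodes the main endothelial growth factor receptor, read between 2.44 and 2.93 on all 4 arrays. FLT1 read 6.12, 5.83, 6.07 and 5.63 on F0 (1), F0 (2), F6 and F12, and FLT4 read 5.82, 4.69, 5.30 and 4.77. AURKB was lower on F12 (7.27) than on F0 (1) (11.40), F0 (2) (9.02) and F6 (10.61), and BIRC5, its partner in the chromosomal passenger complex, read 8.56 on F12 against 11.15 and 10.23 on the F0 arrays. AURKA read 7.92 and 10.80 on the F0 arrays, 10.45 on F6 and 9.85 on F12. The growth factor VEGFA (9.30 on F6, 10.81 on F12) and the histone methyltransferase EZH2 (7.09 and 8.67) lay between the F0 arrays, which read 8.10 and 11.27 for VEGFA and 5.26 and 8.70 for EZH2. ALB (12.41 and 13.58) and AFP (11.95 and 12.60) did so as well. Of 53 endothelial, fibroblast and macrophage markers, 0 were 2-fold above both F0 arrays in F6 or in F12, but only 5 of them reached 6 on F12.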

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

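The tests of label exchange, transplantation rounds, transcript-wide technical effects, cell identity and mouse RNA were chosen after the results were seen. Those of probeset agreement and of single-array spread were written before. The test of label exchange was made to require both fold sizes only after its 4-fold ratio had been seen, and that of mouse RNA to require markers above background only after its result had been seen.

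The median of MAPK pathway output genes lay above both F0 arrays in F6 and below both in F12, and the median difference of F12 from F6 was -1.15. In F6, 0 of 19 members were at least 2-fold above both F0 arrays, while in F12 6 were at least 2-fold below both. Against F0 (1) alone or F0 (2) alone the F6 median (0.51 and 0.63) did not stand apart from random lists, and the F12 median did so against F0 (2) only. FIBIN, a secreted-protein gene, read 4.52 and 4.71 on the F0 arrays, 3.45 on F6 and 7.88 on F12. The F0 and F6 signals of FIBIN are near background (under 6), so its lower F6 value is not evidence of a decrease, and the difference of 4.43 between F12 and F6 is a limit. Camera called the list in F12 against F6 at its preset correlation but not with an estimated one (adjusted p = 0.971), and for FIBIN limma's test of F12 against F6 did not pass.

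The 2 parental arrays differed by at least 4-fold for 4810 genes. If probes of a transcript had been read differently, probesets of the same gene should disagree, but across 1851 genes the F0 differences of the 2 brightest probesets had an r of 0.791, just short of the bound of 0.8 set to exclude this. Subunits of the proteasome, chaperonin, eIF3, RNA polymerase II, coatomer and splicing factor SF3, which dividing cells all need, had an SD of 2.22 between the F0 arrays (74 subunits), against 0.44 between F12 and F0 (2). Over all genes these SDs were 2.01 and 0.58, so the subunits spread much as all genes did. A technical effect on whole transcripts may account for much of the difference, but this test does not single it out. RNA of another cell type in F0 (1) remains open, since 68.8% of the hepatocyte secreted proteins that reached 10 on F0 (2) also did on F0 (1). Apart from RNA of another cell type in F0 (1), no biological explanation for a difference within the parental group was tested.

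F0 (2) lay nearer to F12, and F6 nearer to F0 (1), than the labels would place them. Rounds of transplantation do not account for this order with the labels as given, since F12 lay at 0.963 on the scale between the F0 arrays. An exchange of F0 (2) and F6 stays open: it would group the arrays in the split with 1843 genes, though a technical effect ordering the arrays in that way could give this split too. Against an exchange, the labelled split had 10 times as many genes with a 4-fold gap as the remaining one, where an exchange would make these alike, but this rests on 10 genes against 1, and at a 2-fold gap the ratio was 2.86 (60 against 21 genes). Exchanged labels would also give 3175 genes 4-fold higher in F6 and 3124 in F12, far from the unequal counts of 119 and 2199 in the series description, which shows only which labels those counts were made with.

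F12 lay at least 4-fold beyond all 3 other arrays for 80 genes, BEX1 and VCAM1 among them. F0 (2) did so for 82 genes, a ratio of 0.976, F6 for 5 and F0 (1) for 1284, so single arrays had no common spread. F0 (2) lay near F12 on the scale between the F0 arrays. A gene lower in F12 than in F0 (2) can therefore count for F0 (2). Spread between single arrays could give as many such genes as F12 showed, but this ratio does not settle it. RNA of mouse host cells stays open: 0.0% of 53 endothelial, fibroblast and macrophage markers were 2-fold above both F0 arrays on F12, but only 5 of them reached 6 there, and whether these human probesets read mouse RNA was not tested. Resistance acquired over the rounds stays open and untested, since F12 has 1 array. The series also holds no array of untreated tumors regrafted as often, so drug treatment and regrafting in mice cannot be told apart.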

How the results depend on the processing

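The adjustment for position between the F0 arrays, the counts beyond both F0 arrays and 4 further fits of resistant against parental samples (all probesets singly, repeated quantile normalization, median centring, position between the F0 arrays as a covariate) were chosen after seeing the data. No paired analysis was possible because F6 and F12 have 1 array each. In the fit of 3 groups the adjustment was not run as a test of genes, since it uses up the only residual degree of freedom. As a covariate for resistant against parental samples it left 1 residual degree of freedom, and 0 genes passed.

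The count of genes passing limma stayed at 0 for F6, for F12 against F6 and for resistant against parental samples under every alternative run, including each left-out array for the last. For F12 against F0 the mean of a gene's probesets gave 1 gene, BEX1 (log2 difference 7.61, adjusted p 0.00182), and the other alternatives gave 0. BEX1 has 1 probeset and the same difference in both settings, so its call came only from a changed spread pooled over genes. At the spread of the F0 pair the simulated test missed most changes of log2 6 or less, so the lack of passing genes does not show that genes were unchanged.

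Counts of 4-fold differences depended on the F0 array. Leaving out F0 (1) or F0 (2) gave 388 or 1345 genes higher in F6, 2199 or 47 lower in F6, 113 or 3761 higher in F12 and 149 or 1209 lower in F12. The mean of probesets gave 50 genes lower in F6 and 621 higher in F12. All probesets singly gave 141 higher and 215 lower in F6, and 3004 higher and 459 lower in F12. Removing the F0 axis left 113 genes higher in F12, the same number as leaving out F0 (1), since F12 lay near F0 (2) on that axis. Beyond both F0 arrays, all probesets singly gave 59 in F6 and 183 in F12, against 23 and 116 genes, and the mean of probesets gave 77 in F12. The r between F6 and F12 differences was 0.0359 with F0 (1) as control for F6 and F0 (2) for F12, and -0.843 the other way round. Subtracting different controls shows part of that spread by construction.

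Gene lists standing apart in F6 numbered 13, and 7 or 9 without F0 (1) or F0 (2), of which 4 and 5 were among the 13. In F12 they numbered 10, and 16 after removing the F0 axis. Without F0 (1) they numbered 15, with 7 of the 10 among them, and without F0 (2) 9, with 5 of the 10, the MAPK output and replication lists (-0.91 and -0.44) being among those lost. With an estimated correlation camera could hardly call any list on 1 residual degree of freedom, and it called none in any comparison. At the preset correlation it called some lists in each comparison. Without F0 (1) or F0 (2) the F6 medians reversed for hypoxia-induced genes (-1.20 or 0.58), mitotic genes (-1.20 or 1.78), core and linker histones (1.30 or -0.38), interferon-stimulated genes (0.13 or -0.60), antigen presentation genes (0.25 or -0.62) and unfolded protein and integrated stress response genes (-0.42 or 0.89, and 0.0294 without the F0 axis). Imprinted genes in F12 had a median of -0.0361 with the mean of probesets. In F12 against F6, hepatocyte metabolism genes reversed to 0.302 with a minimum value of 6 on 1 array and 0.0976 without the F0 axis, and DNA methylation genes to -0.0138 without it. Apart from the left-out F0 arrays, the cause was not tested.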

Other observations

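The lists below were fixed before the data were examined, and the adjustment for the position between the F0 arrays was chosen afterwards. For F12, at 0.963 between the F0 arrays, the adjusted value is close to F12 minus F0 (2). An adjusted F12 result is thus not separate from the comparison with F0 (2).

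Of 3 hepatocyte lists, 0 stood apart in F12 against the F0 mean and 2 did after that adjustment. Hepatocyte secreted plasma proteins had an adjusted median of 0.29 (percentile 99.9) and hepatocyte transcription factors 0.42 (percentile 99.6), and both lists were above both F0 arrays (0.37 and 0.26 for the secreted proteins, 0.91 and 0.38 for the transcription factors). Camera called neither list in F12 against F0, at the preset correlation (adjusted p 0.305 and 0.0914) or with an estimated one (adjusted p = 0.895 for both), and with the mean of probesets the unadjusted median of the secreted proteins was 0.04 in place of 0.22. Hepatocyte metabolism genes did not stand apart (adjusted median 0.07, percentile 76.0). Mitotic genes stood apart in the low direction after adjustment, but in the high direction against F0 (1) alone, and camera with an estimated correlation did not call them against the F0 mean (adjusted p = 0.923). Their median in F12 was 2.52 against F0 (1), -1.18 against F0 (2) and -1.06 after adjustment, and 5 of 30 were at least 2-fold below both F0 arrays, among them CCNB1, the mitotic cyclin B1 (9.04 against 10.86 and 10.58), and PTTG1, securin (9.69 against 11.62 and 11.76). Hypoxia-induced genes had a median in F12 of 1.34 against F0 (1), -0.75 against F0 (2) and -0.79 after adjustment (adjusted p = 0.895 in camera with an estimated correlation).

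In F6, interferon-stimulated genes (adjusted median -0.49) and antigen presentation genes (-0.35) were low after adjustment, but their medians against F0 (2) were 0.13 and 0.25, and with an estimated correlation camera called neither (adjusted p = 0.943 for both).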
